A study of Homo sapiens with 6 samples.

How the data were processed

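RNA was sequenced in 6 libraries of H358, an established human line of non-small cell lung cancer with bronchioalveolar features, per the labels. The libraries fall into 3 groups of 2: the parental line with wild-type BRMS1 (WT), and the clones C1 and C2, which the labels call isogenic and list with the BRMS1v2 variant A273V on both copies. Groups and replicate numbers were taken from the sample titles. The labels do not say how the clones were made, whether the replicates of a group are separate cultures, or what the replicate number marks, so p-values measure the spread between these libraries only. Per the labels' protocols, cells grew in RPMI with serum, total RNA was isolated with a column kit, and libraries were read on a HiSeq as 50-nt read pairs.

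The deposited table holds raw read counts per gene, 1 column per library and 57445 genes, followed by 5 HTSeq totals that are not genes, per the file headers. The submitters' processing notes name cutadapt 1.6, STAR 2.5.0a and HTSeq 0.5.3 and the build hg19. They give no strand setting and no annotation release, so reads of overlapping genes on opposite strands cannot be told apart here. Of the 57445 genes, 26710 had no count in any library. Gene counts came to between 27527867 and 37146270 per library, which was 77.6% to 78.7% of the reads listed. Reads outside genes made up 9.77% to 10.7%, ambiguous reads 2.62% to 2.84%, reads aligned to more than 1 place 6.77% to 7.56%, and unaligned reads 1.24% to 2.27%. Replicates of a group were not copies of each other: their counts differed by a chi-square of 100 per gene in WT, 132 in C1 and 117 in C2. Intervals and floors given for counts cover counting error only.

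Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr over the 3 groups, which left 17129, and libraries were scaled by the trimmed mean of M values (TMM). CPM values are on that scale, with a prior count of 2 where log2 values were taken. Each comparison used edgeR's quasi-likelihood F test with robust dispersion, all 6 libraries in 1 fit with 1 mean per group, and Benjamini-Hochberg adjustment over the genes tested, with calls at an adjusted p below 0.05. The comparisons were C1 against WT, C2 against WT, C2 against C1, and the mean of the clones against WT. This model, the gene lists and the rule for named genes were fixed before the data were examined.

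The replicate number was planned as an alternative block. Deviations from the group means of same-numbered libraries correlated across genes by 0.584 between WT and C1, 0.634 between WT and C2 and 0.701 between C1 and C2. All 3 values exceed 0.1, and the first principal component separated the numbers, so the numbers were taken to pair the samples. The pairing comes from the data alone, and with 2 libraries per group the deviations of numbers 1 and 2 are mirror images. If 1 source of variation dominates, numbers given arbitrarily could also yield 3 large correlations of the same sign. The principal component rests on the same values and is not separate evidence. The check therefore cannot show that same-numbered libraries share a condition, and the blocked calls rest on that assumption. Values from the fit with the replicate number as a block, called blocked below, are printed beside the unblocked ones where they differ in call: 1204 genes against 2 in C1, for example. The blocked fit leaves 2 residual degrees of freedom and the unblocked fit 3.

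Genes were named by rule. BRMS1 and FOS are named whatever their values. Shared genes are the 10 that rose and 10 that fell with the largest smaller absolute log2 difference, among genes called in both clones with the same sign, an absolute log2 difference of at least 1 in both and a mean log2 CPM of at least 1. For each clone, the 6 highest and 6 lowest called genes are named with the same level minimum, if both clone libraries lay on the same side of both WT libraries and the gene was not called in the same direction in the other clone. The same 6 and 6 were to be named for C2 against C1, and 4 genes called with opposite signs; none qualified. Pseudogenes, antisense and clone-based loci were skipped. Up to 4 members are named per gene list, plus members whose value is given because they did not pass. The rule takes genes from the comparisons of single clones, where the unblocked calls hold clone-based loci only, so it was applied to the blocked calls. It has no part for the mean of the clones. Genes beyond the rule are named as such, and 1 gene that the rule names for C1 is left out of the text. Gene types, gene order, transcript length and GC content came from GENCODE 29, matched by stable gene ID for 97.3% of the tested genes. That release is on another build than hg19, so no coordinates are given.

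Gene lists, 45 in all, covered transcription factor and signalling targets, lung and other cell type markers, metabolism, stress and library checks. The 41 lists with at least 5 tested members were tested with camera at a preset correlation of 0.01 between genes, with adjustment over lists within a comparison. Camera with an estimated correlation and fry, which tests whether genes move one way (or, mixed, in either direction) without comparing the list with other genes, were run beside it. With 3 residual degrees of freedom, or 2 with the block, the estimated correlation leaves little power. A call lost with it does not show that a list was unchanged. For a gene with no count in a group, a floor of 3 counts over the group gives a lower bound of the ratio. With 1 to 3 counts the ratio is given with its 95% interval. Such genes lie at the low end of their lists, so their bound leaves the list medians where they are.

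On simulated data with 200 changed genes of 16834 tested, in 5 runs, the unblocked test recovered 0% of the 1.5-, 2- and 4-fold changes for C1 against WT and made 0 false calls. The blocked test recovered 13.7%, 72.5% and 98.8% of them for that comparison, and 13.4%, 72.5% and 99.7% for C2 against WT. Of the blocked calls, 17.8% and 16.2% were false, above the nominal level, and C2 against C1 gave 12 false calls per run with nothing changed. A changed simulated list was called in 5 of 5 runs by both fits, and an unchanged list in 0 of 5 runs unblocked and 1 of 5 blocked.

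Alternatives were DESeq2 size factors (RLE) and upper-quartile factors, no filter, a CPM of at least 1 in at least 2 libraries, DESeq2 1.42.0, dispersion without the robust option, the replicate block, the 2 compared groups alone, 2 groups by genotype, glmTreat against 1.5-fold, and each library left out in turn; for lists, the estimated correlation, fry and rank-based camera. For changes shared by the clones, 20 simulations of unchanged clones against the same WT libraries gave the overlap and covariance that shared controls make. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 was used for annotation and figures. No library was left out.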

Results

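Gene expression was measured by RNA sequencing in H358 lung cancer cells, in 3 groups of 2 libraries: the parental line with wild-type BRMS1 (WT) and the clones C1 and C2, both listed with BRMS1v2 A273V on both copies. BRMS1 is a metastasis suppressor that acts in the SIN3-HDAC co-repressor complex. The libraries held 30735129 and 27527867 gene counts in WT, 37146270 and 29857754 in C1, and 29841005 and 32509101 in C2. The comparisons ask how each clone differs from the parental line and whether the clones differ from each other. The series title also names c-fos, so FOS is given beside BRMS1.

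The replicate number marked the largest difference among the libraries. The first principal component (47.6% of the variance) parted replicate 1 from replicate 2 in all 3 groups, and the second (32.7%) parted WT from both clones. Replicate 2 had lower proliferation genes, with 15 of 33 tested members falling and 0 rising, a median log2 difference of -1.99, and an adjusted p of 1.4e-25 by camera (0.7 with an estimated correlation). In replicate 2 of WT, of C1 and of C2, 33 of 33 members were lower, with medians of -1.3, -3.15 and -1.71. In all, edgeR called 2141 genes higher and 2088 lower in replicate 2. Values from the fit with the replicate number as a block are called blocked.

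**Figure D1:**
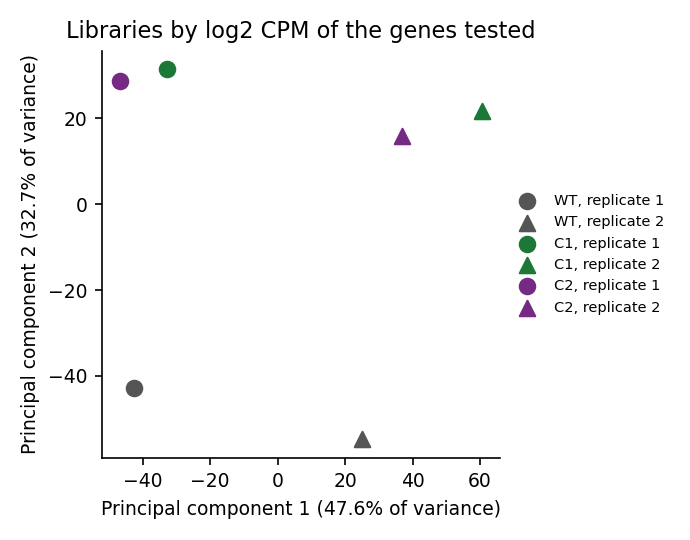
The 6 libraries on the first 2 principal components of the log2 CPM of the tested genes, with the percent of variance on each axis; colour marks the group and marker shape the replicate number. The first axis (47.6%) separates replicate 1 from replicate 2 and the second (32.7%) separates WT from the clones.

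BRMS1 (ENSG00000174744.9) was expressed in all 6 libraries, and its transcript was lower in both clones. Its counts were 1341 and 1030 in WT, 951 and 899 in C1, and 815 and 813 in C2. The mean level was 38.8 ± 5.81 CPM in WT, 28.5 ± 2.23 in C1 and 26.9 ± 2.43 in C2 (SD, n = 2 each). The log2 difference was -0.45 in C1 (SE 0.21, 95% interval -0.95 to 0.05) and -0.53 in C2 (SE 0.21, -1.03 to -0.03), and neither passed the threshold in edgeR (adjusted p 0.69 and 0.73). Blocked, the differences were -0.44 (-0.82 to -0.06, adjusted p 0.17) and -0.53 (-0.91 to -0.14, adjusted p 0.12). The intervals are not adjusted for the number of genes tested. Gene counts do not show the allele, so they do not check the genotype in the labels.

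The lower BRMS1 count was shared with the genes that follow it on chromosome 11. On that chromosome, 664 tested genes had a mean log2 CPM above 2, and only these are counted here. The 302 from BRMS1 to the end had a median log2 difference of -0.37 in C1 and -0.35 in C2. That is 0.772 and 0.784 of the WT level. The 362 genes before BRMS1 had medians of -0.02 and -0.01. Of the 302 genes, 90.1% were lower in C1 and 90.7% in C2, against 52.5% and 50.8% of the genes before it. With the block, 36 of them fell in C1 and 24 in C2, and 2 rose in each. The medians within replicate numbers ranged from -0.39 to -0.33 for the 302 genes and from -0.04 to 0.05 for the others. The clones did not part here, with a median of 0.01 for C2 against C1. This region was chosen after its values were seen, and it holds BIRC3 and GLB1L2, which are named below.

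**Figure D2:**
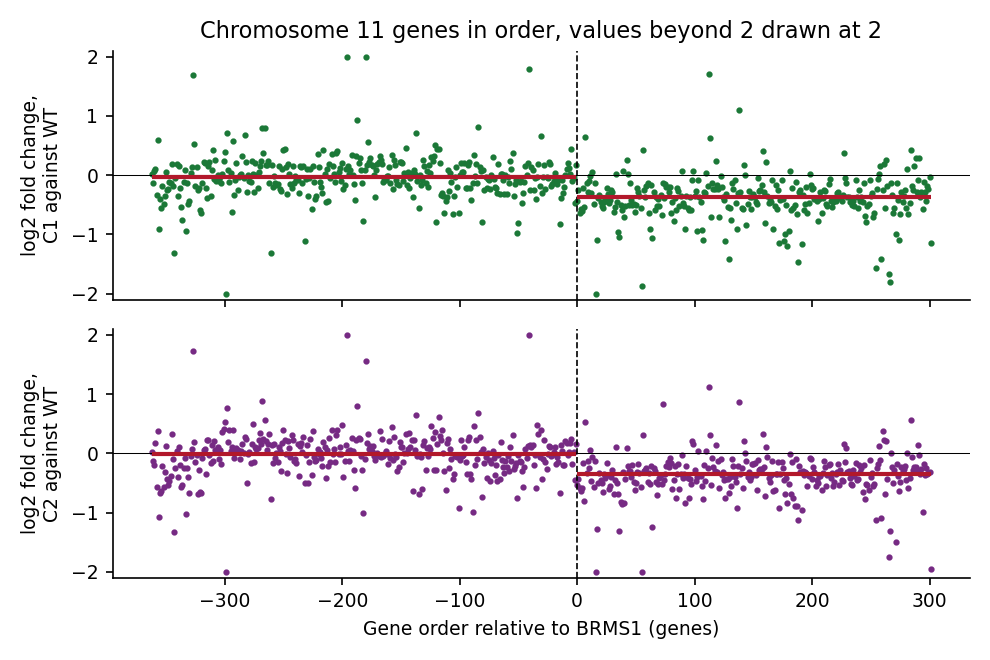
Blocked log2 difference from WT of each tested chromosome 11 gene with a mean log2 CPM above 2, for C1 and C2. Genes are in order relative to BRMS1, with values beyond 2 drawn at 2. From BRMS1 on, the medians are -0.37 in C1 and -0.35 in C2, against -0.02 and -0.01 before it.

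FOS (ENSG00000170345.5), the c-fos transcription factor gene, did not pass the test in either clone. Its counts were 310 and 469 in WT, 440 and 504 in C1, and 215 and 347 in C2, or 12.8 ± 4.15, 14.6 ± 3.11 and 9.14 ± 2.26 CPM (SD, n = 2 each). The log2 difference was 0.19 in C1 (SE 0.35, 95% interval -0.65 to 1.03, adjusted p 0.97 in edgeR) and -0.49 in C2 (SE 0.35, -1.33 to 0.35, adjusted p 0.91). With the block, the intervals were -0.25 to 0.66 in C1 and -0.94 to -0.02 in C2 (adjusted p 0.63 and 0.24). C2 against C1 gave -0.68 (-1.52 to 0.17, adjusted p 1), and -0.69 with the block (-1.14 to -0.23, adjusted p 0.93). The intervals are not adjusted for the number of genes tested. The sign in C1 rests on single libraries: it was -0.1 without WT replicate 1 and -0.04 without C1 replicate 2.

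**Figure D3:**
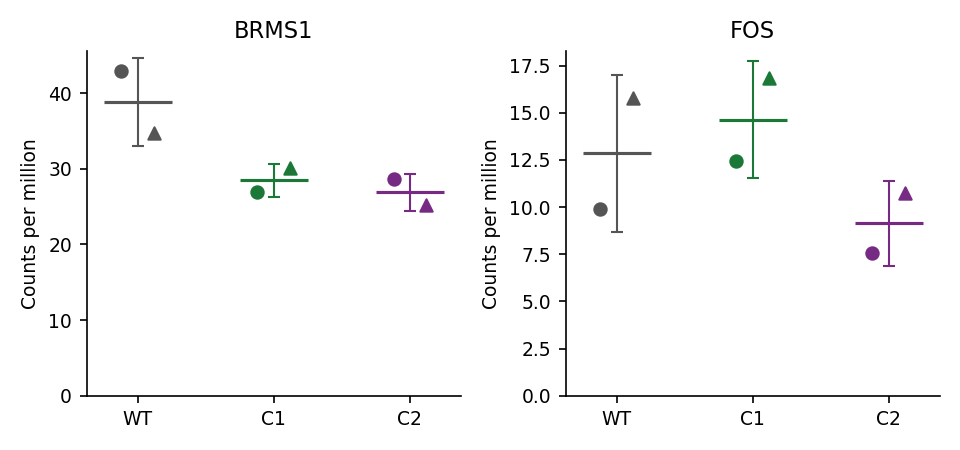
CPM of BRMS1 and FOS in each library by group, with circles for replicate 1 and triangles for replicate 2; horizontal lines are means and bars the SD of 2 libraries. BRMS1 means are 38.8, 28.5 and 26.9 CPM in WT, C1 and C2, and FOS means are 12.8, 14.6 and 9.14.

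C1 both lost and gained transcripts against the parental line. CTSH, a lysosomal cysteine protease, went from 23.4 ± 13.4 CPM in WT to 0.269 ± 0.14 (SD, n = 2 each), and CEACAM6, a surface adhesion glycoprotein, from 28.6 ± 9.75 to 244 ± 131. With the block, 1204 genes were called, 507 higher and 697 lower, of which 187 and 530 changed at least 2-fold. Among genes called in C1 and not in C2, LCN2 (log2 difference 2.76), a siderophore-binding protein, the estrogen sulfotransferase SULT1E1 (2.15), the kinesin KIF26B (1.59), SNED1 (1.42), GLDN (1.42) and ANKRD35 (1.36) rose. MCOLN2 (-3.05), a lysosomal channel, NRK (-2.16), the transporter SLCO4C1 (-2.06), the collagen VI chain COL6A2 (-2.04) and fibulin 1, FBLN1 (-1.80), fell. Their SE lay between 0.28 and 0.5 and their adjusted p between 0.0011 and 0.026 (0.26 to 0.71 without the block). C2 had values of the same sign for all 11, and none passed the test of C2 against C1 (adjusted p of 0.74 or more with the block).

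Without the block, edgeR called 2 genes in C1, both clone-based loci that fell, with 1348 genes at an unadjusted p under 0.05. RP11-314O13.1 went from 34.2 ± 6.42 CPM in WT to 0.168 in C1 and 0.227 in C2 (adjusted p 0.0138 and 0.0168). AC104389.28 held 412 counts in WT and 2 in each clone, a ratio of 221 in C1 (95% interval 60.7 to 1830) and 205 in C2 (56.5 to 1700), with adjusted p 0.0228 and 0.0246; in GENCODE 29 its locus overlaps HBE1, so the share of each is uncertain. These 2 fall outside the rule for named genes. DESeq2 without the block called 270 genes in C1. Leaving out C2 replicate 1 or 2 reduced the blocked count for C1 to 178 or 199, and 17.8% of the blocked calls for this comparison were false on simulated data.

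In C2, MUC13, a transmembrane mucin, went from 0.439 ± 0.193 CPM in WT to 3.92 ± 0.604, and IFI27, an interferon-induced gene, from 161 ± 90.6 to 9.43 ± 6.51 (SD, n = 2 each). With the block, 777 genes were called, 333 higher and 444 lower, of which 134 and 343 changed at least 2-fold. Among genes called in C2 and not in C1, PSG9 (2.00), a pregnancy-specific glycoprotein, the B-lineage transcription factor PAX5 (1.66), the actin-capping TMOD1 (1.6), CYTH4 (1.57), WFDC3 (1.54) and SPANXC (1.46) rose. ZBED3 (-2.38), GLB1L2 (-1.95), the co-repressor TLE2 (-1.54), NPDC1 (-1.53), the AP-1 member JDP2 (-1.47) and NYNRIN (-1.42) fell. Their SE lay between 0.27 and 0.44 and their adjusted p between 0.0058 and 0.044 (0.4 to 0.88 without the block). C1 had values of the same sign for all 12, close to 0 for JDP2 (-0.12), and none passed the test of C2 against C1 (adjusted p of 0.74 or more with the block). PSG9 and SPANXC belong to near-identical families, and their counts are uncertain.

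Without the block, the same 2 clone-based loci were called in C2, with 1156 genes at an unadjusted p under 0.05, and DESeq2 called 209. The blocked count for C2 was unstable: it fell to a few genes without either C2 library and rose without any WT or C1 library. Leaving out a library lowers the residual degrees of freedom of the blocked fit below 2. The blocked count for C1 also fell without a C2 library, though C2 is not part of that comparison. The fall therefore does not show that the calls rest on the library left out. On simulated data, 16.2% of the blocked calls for C2 against WT were false.

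Both clones shared part of their changes. With the block, 623 genes were called in the same direction in both, 269 higher and 354 lower, and 0 in opposite directions. The genes that rose were DHRS9 (log2 difference 3.84 in C1 and 3.27 in C2), a retinol dehydrogenase family member, the copper-dependent ferroxidase HEPH (3.46 and 3.10), netrin G1, NTNG1 (2.95 and 3.90), the secreted lipocalin PAEP (3.02 and 2.85), PRR5L (2.69 and 2.75), MUC13 (2.54 and 3.23), CEACAM6 (3.02 and 2.52), calretinin, CALB2 (2.84 and 2.51), BTBD11 (2.46 and 2.98) and SPANXD (2.27 and 2.59). SPANXD and CEACAM6 have near-identical relatives, so their counts are uncertain. Their SE lay between 0.16 and 0.46, and their adjusted p values between 4.8e-07 (CEACAM6 in C1) and 0.0045 (HEPH in C2) with the block and between 0.12 and 0.63 without it.

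The shared losses included genes with no count left in either clone. FAM133A held 449 counts in WT and 0 in both clones, at least 160-fold lower in C1 and at least 149-fold lower in C2. POF1B, an actin-binding epithelial gene, held 404 and 0, at least 144-fold and at least 134-fold lower. HBE1, embryonic globin, whose locus overlaps AC104389.28, held 1203 counts in WT and 1 in C1, a ratio of 1290 (95% interval 231 to 50900), and had a log2 difference of -7.89 in C2. CTSH (-6.39 in C1 and -5.83 in C2), the mitochondrial thiolase ACAA2 (-4.14 and -4.29), SLC22A31 (-4.10 and -4.54), the flippase ATP8B2 (-4.31 and -3.89), IFI27 (-3.38 and -4.17), NCR3LG1 (-3.50 and -3.34), the ligand of an NK cell receptor, and PNMA2 (-3.28 and -3.25) also fell. SE of the log2 differences printed here lay between 0.21 and 0.48. Adjusted p values of these 10 ranged from 3.1e-07 to 0.00027 with the block, and from 0.057 (HBE1 in C1) to 0.45 (IFI27 in C1) without it.

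**Figure D4:**
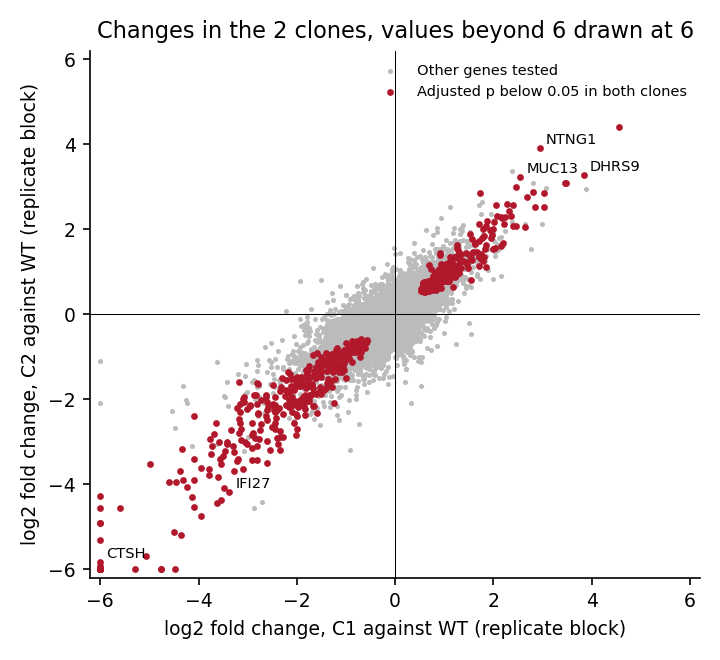
Blocked log2 difference from WT in C1 (horizontal) against C2 (vertical) for each of the 17129 tested genes, with the 623 genes called in both clones in red and values beyond 6 drawn at 6. Of these, 269 lie higher and 354 lower in both clones.

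Both comparisons use the same WT libraries, which alone makes them alike. Independent lists of these sizes would share 9.9 higher and 18.1 lower genes, and simulated unchanged clones shared 1.2 higher and 0.9 lower on average (at most 11 in 20 simulations). The covariance of the log2 differences was 0.396, against 0.051 in the simulations, a difference of 0.345 (unblocked 0.395 against 0.134). The correlation across genes, which are not independent replicates, was 0.878, against 0.501 simulated. The WT libraries cannot be split into sets of 2 libraries, so part of the overlap may come from them. The overlap was 2 without the block, and with it 2 without C2 replicate 1, 8 without C2 replicate 2, and 1006 and 954 without WT replicates 1 and 2.

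Interferon-stimulated genes were lower in both clones, with no member called higher. Members' values here and below are blocked, and list medians and camera values are unblocked unless said otherwise. Of 34 tested members, 13 fell and 0 rose in C1 with the block (19 fell, adjusted over the list alone), and 13 fell and 0 rose in C2 (18 adjusted over the list alone). ISG15 (-1.81 in C1 and -1.73 in C2), a ubiquitin-like protein, IFI6 (-2.63 and -2.38), the antiviral GTPase MX1 (-1.83 and -2.01) and IFI27 fell. The median log2 difference was -0.56 in C1 and -0.62 in C2, with adjusted p 3.2e-11 and 4e-11 by camera. With an estimated correlation the adjusted p was 0.61 and 0.79. The call held without each of the 6 libraries, with adjusted p up to 0.00069 in C1 and 0.0014 in C2. Replicate 2 also had lower values of this list than replicate 1 (median -0.52).

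Mucins and secretory genes were higher in both clones, but in a mixed way. Of 19 tested members, 6 rose and 4 fell in C1 (9 and 5 adjusted over the list alone) and 5 rose and 3 fell in C2 (10 and 5). CEACAM5 (2.64 in C1 and 2.04 in C2), MUC4 (1.99 and 1.53) and CEACAM6 rose, and the protease inhibitor SLPI (-4.09 and -3.40) fell. CEACAM5 shares sequence with CEACAM6, so both counts are uncertain. The medians were 0.62 and 0.67, with adjusted p 0.0012 and 0.0028 by camera (0.67 and 0.79 with an estimated correlation). Without WT replicate 1 the adjusted p was 0.096 in C1 and 0.23 in C2, and without C2 replicate 2 it was 0.65 in C2. This list was also higher in replicate 2 than in replicate 1 (median 1.3).

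Genes of the AP-1 family were lower as a group, and FOS was not among the members that fell. With the block, 0 of 17 rose, 2 fell in C1 and 4 fell in C2 (3 and 4 adjusted over the list alone). BATF had 82 counts in WT and 1 in each clone, a ratio of 87.8 in C1 (95% interval 15.3 to 3510) and 81.8 in C2 (14.3 to 3270). MAF fell by 4.77 on the log2 scale in C1 and went from 222 counts to 0 in C2, at least 73.8-fold lower. JDP2 (-1.47) and JUNB (-0.81) fell in C2. The medians were -0.19 and -0.26, with adjusted p 0.029 and 0.0011 by camera (0.67 and 0.79 with an estimated correlation). The call was lost without WT replicate 2 (0.29) or C1 replicate 1 (0.48) in C1, and without C2 replicate 1 (0.067) in C2. Immediate early genes were not called (adjusted p 0.55 in C1 and 0.34 in C2): with the block, 1 of 30 rose and 4 fell in C1, and 0 rose and 1 fell in C2.

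Squamous and basal genes were lower in both clones. With the block, 3 of 7 fell in C1 and 1 in C2, and 0 rose (0 up and 4 down in C1, 1 up and 3 down in C2, adjusted over the list alone). S100A2 fell in both (-1.80 and -1.39), and SFN (-1.30) and the keratin KRT6A (-1.85) in C1. The medians were -1.36 and -0.89, with adjusted p 0.00066 and 0.017 by camera (0.61 and 0.79 with an estimated correlation). Without C2 replicate 1 the C2 value was 0.054.

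TGF-beta target genes were lower in both clones. With the block, 1 of 19 rose and 5 fell in C1 and 0 rose and 4 fell in C2 (1 and 5, and 0 and 5, adjusted over the list alone). The inhibitors of differentiation ID2 (-2.16 and -1.85), ID3 (-1.62 and -1.24) and ID1 (-0.77 and -0.87), which are also targets of BMP signalling, and the matrix protein THBS1 (-1.49 and -1.21) fell in both clones. The medians were -0.2 and -0.07, with adjusted p 0.015 and 0.023 by camera (0.61 and 0.79 with an estimated correlation). In C1 the call was lost without WT replicate 1 (0.073) or C1 replicate 1 (0.12), and in C2 without WT replicate 1 (0.17) or C2 replicate 2 (0.085).

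RAS-MAPK output genes were slightly higher in both clones. With the block, 3 of 20 members rose and 1 fell in C1. In C2, 2 rose and 0 fell (8 and 1 in each clone, adjusted over the list alone). SPRY1 (0.61), PHLDA1 (0.60) and DUSP6 (0.80) rose and EGR1 (-1.08) fell in C1, and DUSP4 (0.66) and DUSP5 (0.58) rose in C2. The medians were 0.27 and 0.21, with adjusted p 0.029 and 0.034 by camera (0.61 and 0.79 with an estimated correlation). In C1 the call was lost without WT replicate 2 (0.29) or C1 replicate 1 (0.17), and in C2 without WT replicate 2 (0.28), C2 replicate 1 (0.092) or C2 replicate 2 (0.076).

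NF-kappaB target genes and cytokine genes were lower in C1. With the block, 1 of 25 NF-kappaB target genes rose and 4 fell (1 and 6 adjusted over the list alone), and 0 of 22 cytokines and chemokines rose and 3 fell (0 and 5). BIRC3 (-1.14) and LTB (-2.76) fell and TRAF1 (1.07) rose in the first list, and IL11 (-1.19) and CXCL16 (-1.75) fell in the second. Camera gave adjusted p 0.018 for the first (median -0.35) and 0.0084 for the second (median -0.54), each 0.61 with an estimated correlation. Without C1 replicate 2 these became 0.12 and 0.13. In C2 the values were 0.063 and 0.078. With the block the first was called in C2 (0.049, and 0.79 with an estimated correlation), with 1 member up and 2 down.

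Mesenchymal and neuroendocrine genes were also called lower in C1. Of 21 mesenchymal genes, 5 fell and 0 rose with the block (7 and 0 adjusted over the list alone): COL5A1 went from 156 counts to 0, at least 55.7-fold lower, and COL3A1 (-3.95), N-cadherin, CDH2 (-1.34), and the receptor AXL (-1.22) fell. Camera gave adjusted p 0.02 (median -0.16), and 0.61 with an estimated correlation. Without WT replicate 2 it was 0.15, without C1 replicate 1 0.075 and without C1 replicate 2 0.052. In C2, 3 members fell and the list was not called (0.47), with a median of 0.09 (-0.04 blocked), a mean of -0.31 and a test direction of down. Of 5 neuroendocrine genes, UCHL1 (-1.15) and the enolase ENO2 (-0.74) fell in C1 and 0 rose (3 fell, adjusted over the list alone), with an adjusted p of 0.0084 by camera, 0.61 with an estimated correlation and a median of -0.88. In C2 the value was 0.063, with 0 members called.

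Growth and metabolic lists followed the clones unevenly. Proliferation genes were lower in C1, with 5 of 33 falling and 0 rising with the block, among them MYBL2 (-0.95) and CCNE1 (-1.08), a median of -0.42 and adjusted p 0.029 by camera (0.87 with an estimated correlation). The blocked median was -0.87, and the medians within replicate numbers 1 and 2 were -0.21 and -1.83. The direction turned without WT replicate 1 (0.37) and without C1 replicate 2 (0.023), and in C2 the list was not called (0.97, median 0.03, and -0.12 blocked). ATF4 and amino acid genes were higher in C1 (adjusted p 0.032, median 0.15, 0.87 with an estimated correlation), where SHMT2 (0.84) and VLDLR (0.81) rose, and 0 of 23 fell. Without WT replicate 1 the direction turned (0.49), and without C1 replicate 2 the call was lost (0.28). In C2 they were lower (0.0011, median -0.64, 0.79 with an estimated correlation), with 5 of 23 falling and 0 rising, among them the amino acid transporters SLC7A5 (-1.23) and SLC3A2 (-0.98), the pseudokinase TRIB3 (-1.18) and STC2 (-1.14). That call was lost without WT replicate 2 (0.69) or C2 replicate 1 (0.84). Adjusted over the list alone, 5 proliferation genes fell in C1, 3 ATF4 genes rose in C1, and 1 rose and 6 fell in C2. Replicate 2 had higher ATF4 genes than replicate 1 (median 0.73).

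Mitochondrially encoded genes were higher in both clones and cholesterol synthesis genes in C2. For the 13 mitochondrially encoded genes the medians were 0.3 and 0.41, with adjusted p 0.045 and 0.0027 by camera (0.87 and 0.79 with an estimated correlation). With the block, MT-CO3 rose in both (0.54 and 0.60) and MT-ND6 in C2 (0.58), and 0 fell (2 and 12 rose, adjusted over the list alone). The call in C1 was lost without C1 replicate 1 (0.82) and turned without WT replicate 2 (0.8), and that in C2 was lost without WT replicate 2 (0.7) or C2 replicate 1 (0.37). These genes took 6.84%, 7.45% and 8.03% of the counts of replicate 1 of WT, C1 and C2, and 4.28%, 5.4% and 5.99% of replicate 2. Cholesterol synthesis genes had a median of 0.31 in C2 (adjusted p 0.034, 0.79 with an estimated correlation), with 0 of 23 passing with the block. Without WT replicate 2 the value was 0.21, and without C2 replicate 2 the direction turned (0.98).

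**Figure D5:**
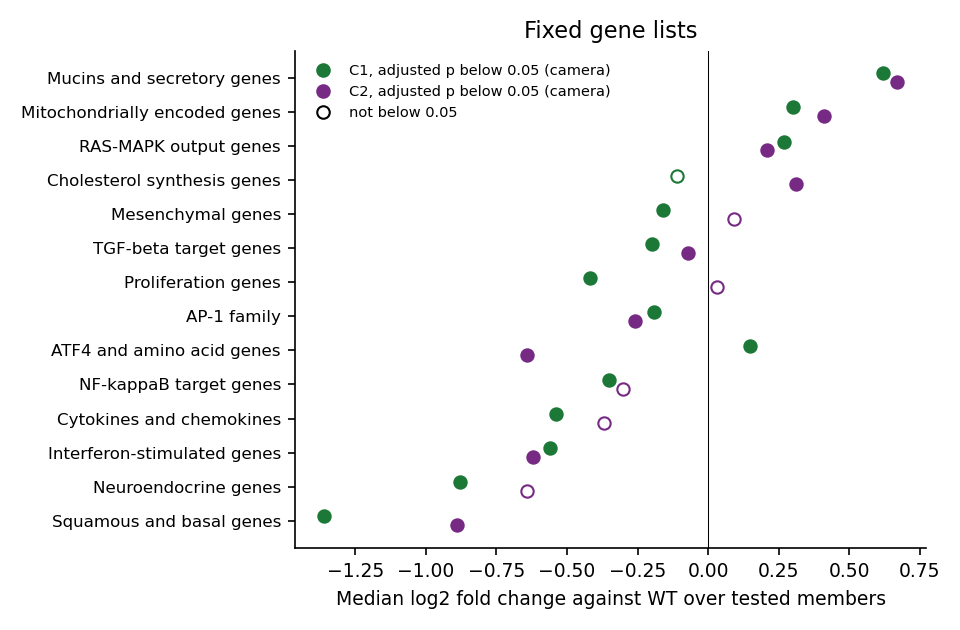
Median unblocked log2 difference from WT over the tested members of each gene list called in C1 or C2, with filled points for an adjusted p below 0.05 by camera at a preset correlation. Squamous and basal genes lie lowest (-1.36 in C1 and -0.89 in C2) and mucins and secretory genes highest (0.62 and 0.67); no call held with an estimated correlation.

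In all, camera called 13 of 41 lists in C1 (4 up, 9 down) and 9 in C2 (4 up, 5 down), and 14 and 10 with the block. The further call with the block in C1 was WNT target genes, which were lower (adjusted p 0.017, and 0.73 with an estimated correlation; 0.09 without the block), with TCF7 (-2.11) among the 2 of 8 that fell. With an estimated correlation 0 lists were called in either clone, with smallest adjusted p 0.61 and 0.79 by camera. This included lists with an estimated correlation below 0 in C1, TGF-beta target (-0.012) and RAS-MAPK output genes (-0.00094). For these lists, the lost calls therefore do not show that correlated genes made them. Other called lists in C1 had estimates far above the preset 0.01. Among them were mitochondrially encoded (0.98), proliferation (0.91), ATF4 (0.74), interferon-stimulated (0.47), mucin (0.38) and squamous genes (0.3). Camera at the preset correlation treats genes of such lists as nearly independent, so its p-values there may be too small. The directional test of fry called 0 lists, and fry called 11 and 5 for change in either direction (30 and 28 with the block).

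Genes linked to BRMS1 in earlier work changed both ways and were not called (adjusted p 0.57 and 0.97). Of the 5 tested, PLAU, urokinase, rose (0.97 in C1 and 0.78 in C2), and osteopontin, SPP1 (-2.23 and -1.79), and BIRC3 (-1.14 and -0.92) fell with the block. In the SIN3-HDAC complex (0.32 and 0.34), SUDS3 rose in both clones (0.58 and 0.55).

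For C2 against C1, no gene passed in the edgeR fit of all 6 libraries with the planned filter. It gave 0 of 17129 genes without the block (61 at an unadjusted p under 0.05, and 0 by DESeq2 with 56) and 0 with it (642 at an unadjusted p under 0.05, and 20 lower genes by DESeq2). With the block, edgeR called 90 genes without a filter, and 102, 90, 343 and 62 without WT replicate 1, WT replicate 2, C1 replicate 1 and C1 replicate 2. Gene lists did part: ATF4 and amino acid genes were lower in C2 than in C1 (median -0.74, adjusted p 2.4e-39 by camera), and cholesterol synthesis (0.48, 7.2e-18), proliferation (0.43, and 0.74 blocked, 8.7e-07), mesenchymal (0.29, 0.00021), fatty acid synthesis (0.34, 0.00049) and squamous and basal genes (0.32, 0.022) were higher. ER chaperone genes (-0.12, 0.022) and the AP-1 family (-0.1, 0.041) were lower. With an estimated correlation the adjusted p was 0.46 for the ATF4, cholesterol, mesenchymal, fatty acid and ER chaperone lists, 0.84 for the squamous and AP-1 lists and 0.85 for proliferation. With the block, mitochondrially encoded genes (0.0061) and cytokines and chemokines (0.046) were also called higher in C2, with adjusted p 0.85 and 0.83 with an estimated correlation. No member of these lists passed over all genes, and adjusted over the list alone 15 ATF4 genes and 1 AP-1 gene were lower and 2 proliferation genes higher with the block. The medians within replicate numbers 1 and 2 were -1.17 and -0.47 for ATF4, 0.05 and 0.82 for cholesterol and 0.23 and 1.81 for proliferation genes.

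With each library left out, only the ATF4 call held for C2 against C1 in all 6 cases (adjusted p up to 1.8e-05). The direction of the proliferation list turned without C1 replicate 2 (8.1e-06) and without C2 replicate 1 (0.034), that of the squamous list without C1 replicate 2 (0.65) and that of the AP-1 list without C1 replicate 2 (0.92). The cholesterol call was lost without C2 replicate 2 (0.12), the squamous call also without it (0.52), and the AP-1 call also without WT replicate 1 (0.085), WT replicate 2 (0.078) and C2 replicate 1 (0.8). Mesenchymal genes lost it without C1 replicate 1 (0.058) and C2 replicate 2 (0.5), fatty acid genes without the same 2 (0.069 and 0.59), and ER chaperone genes without C1 replicate 1 (0.38), C2 replicate 1 (0.081) and C2 replicate 2 (0.25).

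For the mean of the clones, edgeR called 34 genes against WT without the block, 4 higher and 30 lower, and 1669 with it, 705 higher and 964 lower. Of the 34, PAEP (unblocked log2 difference 2.93, adjusted p 0.0414), PRR5L (2.72, 0.0414), LRRC4 (1.94, 0.0419) and the clone-based locus RP11-527H14.3 (2.34, 0.0414) were higher. The lower ones included HBE1 (adjusted p 0.0108), PNMA2 (0.0217), CTSH (0.0278), FAM133A, POF1B, ATP8B2, ACAA2 and SLC22A31 (0.0414 each), named above, and the adenylate kinase AK4 (-3.29, 0.0224) and the transcription factor SALL2 (-6.64, 0.0278). LRRC4, RP11-527H14.3, AK4 and SALL2 fall outside the rule and were chosen after their values were seen. BRMS1 had a log2 difference of -0.49 (adjusted p 0.45), and -0.48 with the block (0.061), and FOS -0.15 (0.93), which was 0.23 without WT replicate 2. The spread here is between libraries of a clone, so it does not extend to further clones. With 2 groups by genotype, in which the difference between clones enters the spread, 142 genes were called. That fit treats libraries of the same clone as independent, so it does not extend to further clones either. Without single libraries the unblocked count fell to between 0 (WT replicate 1, C1 replicate 1) and 3 (C1 replicate 2, C2 replicate 2), with 1 without WT replicate 2 or C2 replicate 1. The blocked count fell to 208 and 213 without C2 replicates 1 and 2.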

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

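The test of C2 against C1 was planned, and it marked 8 gene lists in which the clones differed from WT by different amounts by camera at a preset correlation. The median log2 difference of C2 from C1 was -0.74 for ATF4 and amino acid genes, -0.12 for ER chaperone genes and -0.1 for the AP-1 family. It was 0.48 for cholesterol synthesis genes, 0.43 for proliferation genes, 0.34 for fatty acid synthesis genes, 0.32 for squamous and basal genes and 0.29 for mesenchymal genes. No list was marked with an estimated correlation (smallest adjusted p 0.46), and of the 8 the ATF4 list alone kept its call without each of the 6 libraries. No group has enough libraries for a test of outlying samples.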

How the results depend on the processing

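The settings for the unblocked fit were planned before the data were examined, and the further settings of the blocked fit were chosen after the pairing check. Without the replicate block, RLE and upper-quartile factors, the CPM filter and dispersion without the robust option kept every count of called genes within 1.5 times. No filter moved the counts to 296 (C1 against WT), 209 (C2 against WT), 436 (mean of clones) and 177 (both clones), and DESeq2 to 270, 209, 393 and 178. The replicate block moved them to 1204, 777, 1669 and 623. The 2 compared groups alone gave 1 in C1, 0 in C2 and 0 in both clones. glmTreat against 1.5-fold gave 9 for the mean of clones, and 2 groups by genotype 142. C2 against C1 stayed at 0 in edgeR under every unblocked setting run, and in DESeq2, with 61 and 56 genes at an unadjusted p under 0.05. For genes with no count, depth sets the limit: 3 counts over the WT libraries are 0.051 CPM.

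Without single libraries, the unblocked counts ranged from 0 to 1 in C1, 0 to 0 in C2, 0 to 3 for the mean of clones and 0 to 0 in both clones. The blocked counts ranged from 178 to 1776 in C1, 2 to 1756 in C2, 0 to 343 for C2 against C1, 208 to 2277 for the mean of clones and 2 to 1006 in both clones; the lowest came without C2 replicate 1 in each, and for C2 against C1 also without C2 replicate 2. A group left with 1 library is assumed to vary like the others. The blocked fit then has fewer than 2 residual degrees of freedom, so a low count does not show which library the calls rest on. Of the 777 genes called in C2, 2 were shared with the fit without C2 replicate 1 and 7 with that without C2 replicate 2. With the replicate block and no filter, the counts were 2074 (C1), 1550 (C2), 90 (C2 against C1), 2598 (mean) and 1158 (both). With the block, glmTreat gave 317, 227, 393 and 194 for all but C2 against C1, and DESeq2 20 genes for C2 against C1. The 2 compared groups alone use fewer libraries and glmTreat asks for a minimum fold; for the other settings the cause was not tested. The block changed no call of BRMS1 or FOS.

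BRMS1 kept its sign and missed the threshold under every setting run, from -0.59 to -0.28 in C1 and from -0.67 to -0.36 in C2 without single libraries. Without single libraries, FOS ranged from -0.1 to 0.57 in C1 and from -0.44 to 0.23 for the mean of clones, so its sign there depends on them. In C2 FOS kept its sign, but its size ranged from -0.79 without C2 replicate 2 to -0.11 without WT replicate 2. The named genes gave 64 values per setting, none of which changed sign; without the block, DESeq2 took 45 past the threshold, no filter 41 and the other settings none. These genes were picked from the blocked calls, so the blocked fit is no check of them. Signs that hold without single libraries are no check either. The rule for each clone required both clone libraries on the same side of both WT libraries. All 623 shared genes, from which the others were picked, had the same direction within each replicate number.

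For gene lists, 0 were called in C1, C2 or C2 against C1 with an estimated correlation or by the directional test of fry, with or without the block. For change in either direction, fry called 11 in C1, 5 in C2 and 0 for C2 against C1, and 30, 28 and 1 with the block. Without single libraries, the lists called for C2 against C1 numbered 7 to 15. The direction of some calls turned, and the adjusted p without single libraries ranged from 6e-20 to 0.37 (proliferation), 5.7e-06 to 0.49 (ATF4) and 3.7e-06 to 0.82 (mitochondrially encoded) in C1, from 2.1e-05 to 0.98 (cholesterol) in C2, and from 0.011 to 0.92 (AP-1), 2.1e-05 to 0.65 (squamous) and 4e-34 to 0.034 (proliferation) for C2 against C1. Leaving out 1 library unbalances the replicate numbers, which move several of these lists. The rank-based camera ended 7 of 30 calls. The CPM filter ended 1 of the 29 it could test (mitochondrially encoded genes in C1, 0.058), and neuroendocrine genes in C1 were left with too few members; the block kept the direction and call of all 30.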

Other observations

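Tests chosen only after the result was seen were the distance and step tests on chromosome 11, the correlation of libraries that are not shared, the same-clone correlation, the genotype row, the growth test and the moves of other genes by the GC and length corrections; the other tests were set before their value was seen. Several cell identity and signalling genes changed in both clones with the block, in lists that camera did not call. None of the genes named here passed in either clone without the block, and some lists had members called both ways. In C1, 3 epithelial junction genes rose and 3 fell, and 4 extracellular proteases and inhibitors rose and 4 fell. In C2, 0 and 3 rose in these lists and 1 and 0 fell. The tight junction gene CLDN1 fell (-2.06 in C1 and -1.79 in C2), as did the ERBB ligand NRG1 (-2.13 and -1.41), the Notch target HEYL (-3.21 and -2.19), the hair keratin KRT81 (-1.37 and -1.67) and the caveolar gene CAV1 (-1.15 and -1.03). In antigen presentation, CD74, the class II invariant chain, fell (-2.27 and -2.35), and HLA-B rose (0.69 and 0.68). VIL1, an intestinal microvillus gene, rose (1.52 and 1.89) and FOXA3 fell (-2.04 and -2.05). The metalloprotease MMP14 (1.14 and 1.07), the actin-severing GSN (0.99 and 0.89) and the ciliary regulator FOXJ1 (1.46 and 1.18) rose, and the glucose transporter SLC2A3 fell (-2.09 and -2.13).

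List medians and means parted in sign in C1 for metastasis suppressor genes (0.16 and -0.26, tested as down), extracellular proteases (0.18 and -0.07, up), antigen presentation (0.07 and -0.06, up), heat shock (0.02 and -0.01, up), alveolar type 1 (0.02 and -0.54, up) and alveolar type 2 genes (0.05 and -0.48, down). In C2 they parted, besides the mesenchymal list, for keratins of simple epithelium (0.14 and -0.11, up), ER chaperone genes (0.01 and -0.08, down), apoptosis regulators (-0.01 and 0.05, up) and alveolar type 1 genes (0.27 and -0.36, down). None of these was called, and the means include fitted values of genes near 0 counts. Of the markers of other cell types, at least 1 CPM was reached in WT by 3 of 10 fibroblast genes (COL1A1 at 37.9 CPM), 2 of 7 endothelial genes (KDR at 13.9) and 2 of 11 leukocyte genes (CD14 at 2.71); these lists have too few tested members for camera. Of these, COL3A1 fell in both clones (-3.95 and -3.62) and KDR (1.03) and CDH5 (1.82) rose in C1 with the block.

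Genes from BRMS1 to the end of chromosome 11 were lower in both clones, a pattern found and tested on the same data. The median for the mean of the clones stayed at -0.37 after trends with GC content and transcript length were removed. The correction moved 11.8% of the other genes by at least 0.1, so such a trend does not account for the pattern. The 100 genes farthest from BRMS1 had a median of -0.36, against an effect on its neighbours alone. The best step along the chromosome, of 645 positions, fell between RAB1B and YIF1A in both clones, 3 genes from BRMS1; 7 of the positions lie within that distance. Segments of 30 genes were formed along the chromosomes from genes with a mean log2 CPM above 2, the minimum also used for chromosome 11. Of 379 segments, 18 shifted by at least 0.3 in both clones. Such shifts were more frequent on chromosome 11 but not confined to it. Of the 357 segments outside it, 9 shifted, 6 higher (on chromosomes 9, 6 and 14) and 3 lower (on 16, 19 and 8). Loss of a copy of the chromosome end beginning near BRMS1 is a candidate explanation. The median level was 0.772 of WT in C1 and 0.784 in C2. That is a smaller fall than the loss of 1 of 2 copies would give if transcripts followed copy number. Copy number was not measured in WT or the clones, so the size of the fall cannot be set against a known number of copies. It therefore does not argue for or against a loss. Read or array data on DNA would be needed to test this explanation.

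Both clones shared their differences from WT. Clone differences made from libraries that are not shared still correlated across genes by 0.498 or more, and 85.7% of the covariance was left after the medians of 30-gene segments were removed, so neither the shared WT libraries nor copy-number-like segments account for all of it. A common origin of the clones apart from most WT cells stays open: across segments outside chromosome 11 the correlation between libraries that are not shared was 0.259 and 0.481, under the bound of 0.5 set beforehand, but 2 differences of the same clone reached only 0.302 and 0.43, so that bound could not be met here. The BRMS1 genotype and a common origin cannot be told apart, since the series holds 0 clone libraries without the genotype.

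Replicate 2 differed from replicate 1 in all 3 groups. Proliferation genes had a median log2 difference of -1.71 in C2, whose replicate 2 was 1.09 times as deep as replicate 1, so lower depth does not account for it. The median over the groups was -2.04 before and -2.03 after trends with GC content and transcript length were removed, while 49% of the other genes moved by at least 0.1, so such a trend does not account for it. In each group 33 of 33 proliferation genes were lower, so a difference in growth state of the cultures is a candidate explanation. Other lists moved with the number too: mitochondrially encoded (median -0.7, adjusted p 1.1e-08 by camera) and cytosolic ribosomal protein genes (-0.18, 0.027) were lower, and replication-dependent histone genes were higher (0.59, 2.1e-05), with 0.9, 0.9 and 0.7 with an estimated correlation. How histone genes relate to proliferation in these libraries was not tested, so their rise is not counted for or against the growth state. Whether the growth state is the whole cause stays open. The labels do not say what the replicate number marks.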
